A study of Mus musculus with 6 samples.

How the data were processed

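The series measured gene expression in 6 libraries of mouse primary hepatic stellate cells, 3 kept with vehicle and 3 with APB-R3 for 24 h. Per the labels' protocols, RNA was taken with Trizol, and 500 ng of total RNA went into each Lexogen QuantSeq library, a kit that reads 1 fragment near the 3' end of a transcript, so that a count does not grow with gene length. Per the submitters' processing notes, reads were split by sample with bcl2fastq 2.20.0.422 and processed with fastp, STAR and HTSeq on the build GRCm39. The versions and options of the last 3 tools, the annotation release, the handling of unique molecular identifiers and the strand setting of the counting are not given in the sources used here.

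The deposited values are whole-number counts of reads per gene, not normalized, with 40879 gene symbols in each library and no rows for unassigned reads. Totals were 10431310, 10573916 and 10507141 counts in vehicle replicates 1 to 3 and 8323809, 10792531 and 10074669 in APB-R3 replicates 1 to 3. The header inside each file carries the numbers 2, 3 and 4 where the titles have 1, 2 and 3. Each library was given the group and number of its title. Nothing says that molecular identifiers were used, so counts may not be independent molecules and an interval from counting covers counting error only. The predicted gene Gm26917 took between 5.85% and 6.81% of the counts of a library, and mitochondrial ribosomal RNA between 2.09% and 2.76%. Genes are named by the symbols in the files, which hold no other identifiers. The gene annotation at hand was RefSeq for GRCm38.p6, another build, and was used for matching symbols only, so no coordinates are given. Counts of genes with near-identical copies, such as Saa1 and Saa2, Ctla2a, the Serpina3 family and ribosomal protein genes with processed pseudogenes, and of genes that overlap on opposite strands, are uncertain.

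The comparison, its test, the gene lists, the rule for named genes and the alternatives listed here, except where said, were set before the data were examined. Libraries were compared in edgeR 4.0.16 (R 4.3.3) with filterByExpr at its defaults (a minimum count of 10 and a minimum total of 15), TMM factors, and the quasi-likelihood functions glmQLFit and glmQLFTest with treatment as the only term. Of 20496 genes with a count in any library, 12776 were tested. Adjusted p-values are Benjamini-Hochberg values, with a threshold of 0.05. Standard errors of log2 fold changes were taken as the fold change over the square root of the F statistic, and levels are CPM on TMM-scaled library sizes, or on plain library totals for the levels of marker lists and in the closing section. All gene tests are two-sided. The common biological coefficient of variation was 0.145.

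In all, 30 gene lists of pathways, stellate cell states and other liver cell types were written from general knowledge, with 713 entries, of which 712 were found in the files, 17 of them under another symbol. Lists with at least 5 tested members, 28 of them, were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists. Camera with a correlation estimated per list and fry were run beside it. Each list's genes were also adjusted over the list alone. The named genes are the 10 with the largest rise and the 10 with the largest fall among genes that pass with at least 5 CPM in the higher group. Where fewer than 5 pass in a direction, the genes with the smallest p up to 5 are given as not passing, leaving out predicted and unnamed genes. To these come 12 genes of the IL-18 axis and of stellate cell activation in all cases, and for each list up to 4 passing members or, with none, the tested member with the smallest p. Some genes that this rule names are not reported here.

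The scripts were tested on simulated counts drawn from the means, dispersions and sizes of these libraries, with 200 of 12776 genes changed in each of 5 simulations. Over these, edgeR made 529 calls, of which 21 were of unchanged genes. A list lowered 1.25-fold was called by camera in 5 of 5 simulations, by camera with an estimated correlation in 2 and by fry in 4. With no list lowered, camera called 1 list over the 5 simulations, camera with an estimated correlation 0 and fry 1, and beside the lowered list fry called 1 more. Genes were drawn independently of each other in these simulations. The counts of any pair of libraries differed by more than sampling noise, with a chi-square of 5.56 to 13.6 per degree of freedom over genes with at least 20 counts, so no library was a copy of another. The labels used here give no batch or date. The alternatives were DESeq2 size factors, library size only, no low-count filter, at least 5 CPM in 3 libraries, DESeq2 1.42.0 with its Wald test, limma-voom, a block for the replicate number, counts thinned to the smallest library, the 20 most abundant genes left out, and each library left out in turn. Leaving out both APB-R3 replicate 1 and vehicle replicate 2, and limma-voom with a quality weight per library, were added after seeing the data. Intervals of medians in the closing section are 95% bootstrap intervals over genes with 10000 resamples.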

Results

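Primary hepatic stellate cells from wild-type male mice were kept for 24 h with vehicle or with APB-R3, an engineered form of interleukin-18 binding protein (IL-18BP). Stellate cells are the retinoid-storing pericytes of the liver, which turn into contractile, matrix-producing cells when they are activated. IL-18BP is a secreted protein that binds IL-18 and keeps it from its receptor. Messenger RNA was counted at its 3' end in 3 vehicle and 3 APB-R3 libraries. These libraries also held much endothelial RNA. Liver endothelial markers had a median of 292 CPM, contractile genes 137 CPM and genes of quiescent stellate cells 7.15 CPM. All values below, those of activation genes and of the IL-18 axis included, are therefore values of whole cultures. The dose of APB-R3 is given as 150 µg/ml in the series text and as 150 µg/kg in the sample protocol, so its unit is open here. The vehicle libraries held 10431310, 10573916 and 10507141 counts and the APB-R3 libraries 8323809, 10792531 and 10074669. Nothing in the labels says that the replicates came from separate animals or cultures, so all p-values measure only the spread between these samples, which may be technical.

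The series asks whether APB-R3 attenuates stellate cell activation, and its comparison sets APB-R3 against vehicle. Acta2, the smooth muscle actin that marks activated stellate cells, had 131 ± 2.41 CPM in vehicle and 97.3 ± 15.8 CPM in APB-R3 (SD, n = 3 each). All 3 APB-R3 libraries lay below all 3 vehicle libraries, with a log2 fold change of −0.43 (SE 0.11), and the gene did not pass edgeR's test over all genes (adjusted p = 0.9998). Over all alternatives the log2 fold change of Acta2 ran from −0.53 to −0.31. Its adjusted p ran from 0.0523 to 0.99998, so that it passed in none of them. With each library left out in turn, its lowest edgeR adjusted p was 0.626. Among the fibrillar collagen genes, Col1a1 had 142 ± 6.86 CPM in vehicle and 137 ± 19.8 CPM in APB-R3, and Col3a1 had 57.8 ± 3.83 and 59.0 ± 8.25 CPM. Col1a2 had a log2 fold change of −0.25 (SE 0.11) at 130 ± 11.1 CPM in vehicle and 109 ± 14.6 CPM in APB-R3. None of the other activation genes named in advance passed either. The log2 fold change was 0.18 (SE 0.13) for Timp1, an inhibitor of matrix proteases with all 3 APB-R3 libraries above all 3 vehicle libraries, and 0.09 (SE 0.22) for Tgfb1, the main profibrotic cytokine gene. It was −0.09 (SE 0.09) for Ccn2, a target of TGF-beta and YAP signalling, and −0.57 (SE 0.36), or −0.24 without vehicle replicate 2, for Des, the muscle intermediate filament gene found in rodent stellate cells. The 95% interval of the log2 fold change, not adjusted for the number of genes, ran from −0.67 to −0.20 for Acta2, −0.47 to −0.021 for Col1a2, −0.27 to 0.17 for Col1a1 and −0.27 to 0.09 for Ccn2. The direction of Col1a1 turned without APB-R3 replicate 2 (0.04), and that of Col3a1 without vehicle replicate 3 (−0.02) or APB-R3 replicate 3 (−0.09). Tgfb1 turned without vehicle replicate 1 (−0.003) or APB-R3 replicate 3 (−0.05), and Ccn2 without vehicle replicate 2 (0.001).

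The genes of the IL-18 axis had low levels. Il18, which encodes the cytokine, had 0.860 ± 0.347 CPM in vehicle and 1.21 ± 0.581 CPM in APB-R3, a log2 fold change of 0.49 (SE 0.70) that was 0.019 without APB-R3 replicate 2. Il18bp, the mouse gene of the binding protein, had 2.84 ± 1.02 and 3.49 ± 2.14 CPM, a log2 fold change of 0.31 (SE 0.50) that turned to −0.07 without APB-R3 replicate 3. Il18r1 and Il18rap, the subunits of the IL-18 receptor, were below the count filter. Each had 1 count over all 6 libraries, in APB-R3 replicate 1 for Il18r1 and in APB-R3 replicate 2 for Il18rap. That count equals 0.0165 CPM with an exact 95% Poisson interval from 0.000417 to 0.0918 CPM, which covers counting error only. Receptor transcripts were thus hardly counted here. So were some other listed genes, with 10 counts of the glycolysis gene Aldoa and 0 of the mitochondrially encoded COX2 over all 6 libraries. Whether so low a count reflects expression or the assignment of reads to genes was not tested.

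None of the 12776 genes tested passed edgeR's quasi-likelihood test at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 425 genes, 224 higher and 201 lower with APB-R3, which is 3.33% of those tested. DESeq2 and limma-voom also called 0 genes, with 376 and 427 genes at an unadjusted p under 0.05. The groups did not overlap in 566 genes that were higher and 559 that were lower, together 8.81% of the tested genes, where chance gives 10%. In counts simulated with the spread of these libraries, edgeR recovered 10% of changes with a log2 fold change of 0.32, 42% of 1.5-fold, 73.2% of 2-fold and 78% of 3-fold changes. With no filter on low counts 20 genes passed, 8 higher and 12 lower, and 18 of them had their highest CPM in APB-R3 replicate 1 or vehicle replicate 2. Several of the 20, Il1b, Acod1, Mmp9, Hpx and Saa3 among them, were also tested with the filter and did not pass there. The log2 fold change of Il1b was 3.24 in both fits, with an edgeR adjusted p of 4.55e-17 without the filter and 0.9998 with it. The filter thus did not hide these genes, and why their p-values moved was not tested. Without vehicle replicate 3, 1 gene passed, Hp, the plasma protein haptoglobin made by hepatocytes, which is named after its values were seen. Hp had 28, 102 and 1 counts in vehicle replicates 1 to 3 and 1, 2 and 0 in APB-R3, so its highest count was in vehicle replicate 2, the library with the high Hpx level.

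Genes among those with the smallest p in each direction are given as values, since none passed. On the lower side, besides Acta2, Casp12, a caspase of the endoplasmic reticulum, had 20.7 ± 2.74 CPM in vehicle and 12.3 ± 1.64 CPM in APB-R3. The acute-phase gene Saa3 had 17.0 ± 9.53 and 7.72 ± 1.14 CPM, with 28.0 CPM in vehicle replicate 2. Hpx, the haem-binding plasma protein hemopexin made by hepatocytes, had 19.2 CPM in vehicle replicate 2 and between 0.187 and 1.14 CPM in the other 5 libraries. On the higher side, Xpa, a DNA damage recognition factor of nucleotide excision repair, had 19.6 ± 1.03 CPM in vehicle and 29.0 ± 0.494 CPM in APB-R3. Ddx28, a mitochondrial RNA helicase, had 13.2 ± 1.32 and 21.3 ± 2.39 CPM. Mmp9, a gelatin-degrading protease, had 16.1 ± 4.76 and 28.8 ± 7.56 CPM. Acod1, the enzyme that makes itaconate in activated macrophages, had 4.30 ± 1.78 and 12.5 ± 8.22 CPM, and Il1b, the cytokine IL-1 beta, had 36.8 CPM in APB-R3 replicate 1 and between 0.475 and 2.25 CPM elsewhere. Some of these folds rest largely on 1 library. The log2 fold change was 3.24 (SE 0.84) for Il1b and 1.52 (SE 0.38) for Acod1, against 0.21 and 0.87 without APB-R3 replicate 1. It was −3.86 (SE 0.91) for Hpx and −1.14 (SE 0.29) for Saa3, against −1.12 and −0.58 without vehicle replicate 2.

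**Figure D1:**
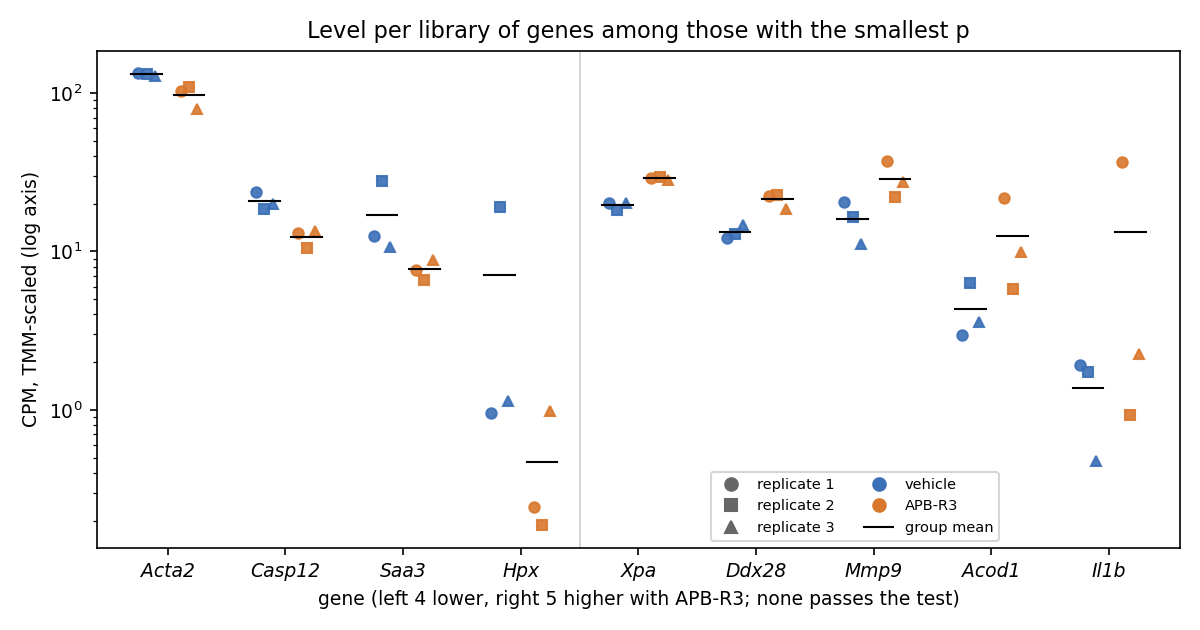
Level in each library of 9 genes among those with the smallest p, in CPM after TMM scaling on a log axis. Blue points are vehicle, orange points APB-R3, the marker shape gives the replicate and the black bar the group mean of 3 libraries; Xpa lies near 19.6 CPM in vehicle and 29.0 CPM in APB-R3, while the means of Il1b and Hpx rest on 1 library each.

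Of the 28 gene lists large enough to test, 5 passed limma's camera test with a preset correlation, and all had small medians. With an estimated correlation none of the 5 passed, each with adjusted p = 0.807, and fry gave adjusted p of 0.618 for the matrix glycoprotein list and 0.748 for the other lists. Genes of cholesterol and fatty acid synthesis were lower in 21 of 25 members, with a median log2 fold change of −0.17 (adjusted p = 0.000434). Of its members 1 passed when adjusted over the list alone, and 0 over all genes. Inflammatory cytokine and NF-kB target genes were higher in 24 of 31 members, with a median of 0.17 (adjusted p = 0.00473), and 8 members passed when adjusted over the list alone, 7 higher and Saa3 lower, against 0 over all genes. Nfkbiz and Cxcl2, among those 8, are named after their values were seen. Nfkbiz had 85.2 ± 2.16 CPM in vehicle and 107 ± 9.36 CPM in APB-R3. The neutrophil chemokine gene Cxcl2 had 262 CPM in APB-R3 replicate 1 and between 38.9 and 59.7 CPM elsewhere. Cell cycle genes were lower in 22 of 33 members (median −0.12, adjusted p = 0.0277), led by the mitotic kinase gene Aurkb at −1.22 (SE 0.43). Matrix glycoproteins and crosslinking enzymes were lower in 14 of 20 members (median −0.08, adjusted p = 0.0297). The smallest p was that of the proteoglycan gene Lum at −1.87 (SE 0.70). Lum had few counts, with 1.94 ± 0.729 CPM in vehicle and 0.536 ± 0.283 CPM in APB-R3. Cytosolic ribosomal protein genes were higher in 34 of 39 members (median 0.06, adjusted p = 0.0297), led by Rps27a at 0.18 (SE 0.09). In each of these last 3 lists 0 members passed when adjusted over the list alone.

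All 5 list calls were lost without APB-R3 replicate 1, the library with the high Il1b and Cxcl2 levels. This library also had the lowest total, and ribosomal protein genes took 3.48% of its counts against 3.08% to 3.18% in the others, mitochondrial ribosomal RNA 2.09% against 2.39% to 2.76% and other mitochondrial transcripts 2.93% against 2.34% to 2.74%. The median was then −0.06 for cholesterol and fatty acid synthesis (adjusted p = 0.15), −0.06 for the cell cycle (0.930), −0.10 for matrix glycoproteins (0.15) and 0.02 for ribosomal proteins (0.939). That of the inflammatory list turned to −0.04 (adjusted p = 0.964). This list was also lost without vehicle replicate 2 (adjusted p = 0.119), where its median stayed at 0.17. The cell cycle list was lost without vehicle replicate 3 as well (median −0.077, adjusted p = 0.270). The matrix glycoprotein list was lost without vehicle replicate 3 (−0.080, 0.0824) or APB-R3 replicate 2 (−0.086, 0.0879), with medians near the −0.085 of all 6 libraries. The ribosomal list was lost without vehicle replicate 1 (0.057, 0.131) or 3 (0.051, 0.148), against 0.064 in all 6 libraries. Over all alternatives the adjusted p ran from 1.46e-05 to 0.807 for cholesterol and fatty acid synthesis, 8.38e-06 to 0.964 for the inflammatory list, 0.00459 to 0.930 for the cell cycle, 0.0115 to 0.807 for matrix glycoproteins and 0.00459 to 0.939 for ribosomal proteins. The number of lists that passed was 0 without APB-R3 replicate 1, 3 without vehicle replicate 3, 8 without APB-R3 replicate 3 and 9 without APB-R3 replicate 2.

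**Figure D2:**
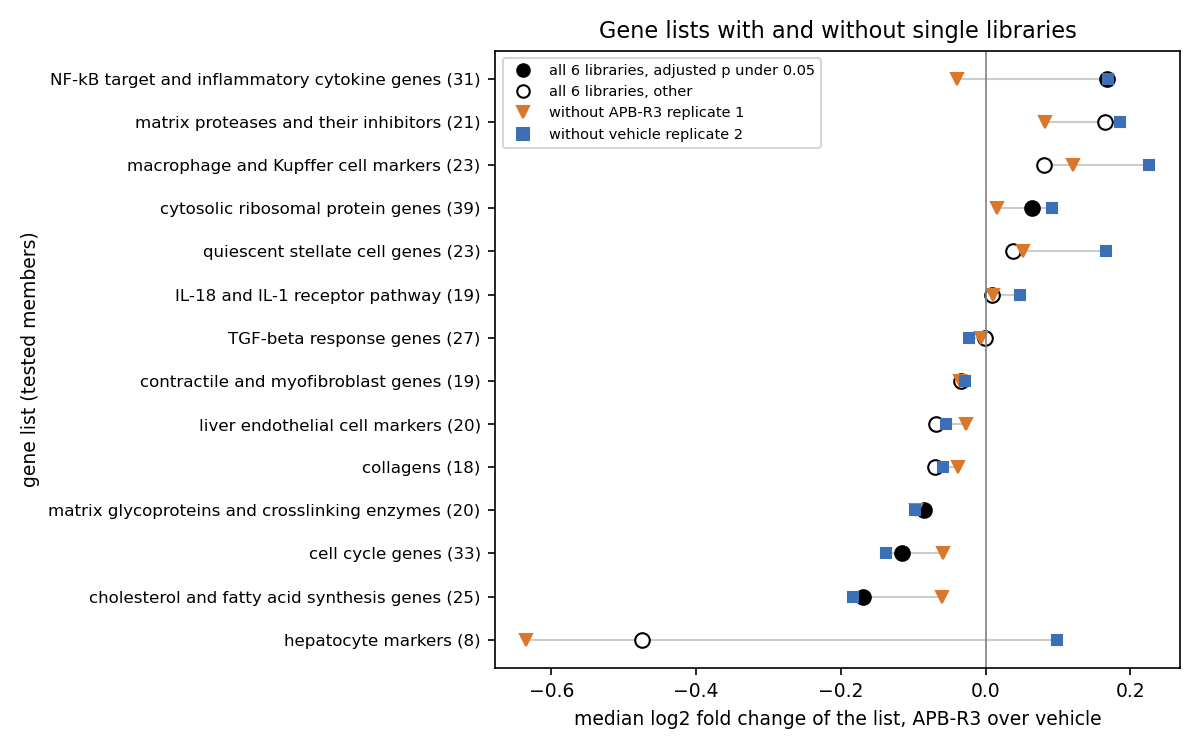
Median log2 fold change, APB-R3 over vehicle, of 14 gene lists, with the number of tested members in brackets. Circles use all 6 libraries and are filled where camera's adjusted p is under 0.05; orange triangles leave out APB-R3 replicate 1 and blue squares vehicle replicate 2, which move the inflammatory median from 0.17 to −0.04 and the hepatocyte median from −0.47 to 0.10.

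The other lists of stellate cell genes did not pass. Collagen genes were lower in 14 of 18 members (median −0.07, adjusted p = 0.132), and Col11a1 had the smallest p at 1.37 (SE 0.54). Col11a1 had few counts, with 1.11 ± 0.355 CPM in vehicle and 2.90 ± 0.746 CPM in APB-R3. The collagen list passed without APB-R3 replicate 3 (median −0.13, adjusted p = 0.00930, with a range over all alternatives up to 0.919). The median was −0.04 without APB-R3 replicate 1. In all 6 libraries the list had 0.807 with an estimated correlation and 0.748 with fry. Contractile genes were lower in 14 of 19 members (median −0.03, adjusted p = 0.300), with Acta2 the only member to pass when adjusted over the list alone. Matrix proteases and their inhibitors were higher in 13 of 21 members (median 0.16, adjusted p = 0.107), and only Mmp9 passed when adjusted over the list alone. The protease list passed without APB-R3 replicate 2 (median 0.18, adjusted p = 0.0278, in a range over all alternatives up to 0.919). Its median was 0.08 without APB-R3 replicate 1. In all 6 libraries it had 0.807 with an estimated correlation and 0.748 with fry. Genes of quiescent stellate cells were higher in 15 of 23 members (median 0.04, adjusted p = 0.163), with Prelp, a small matrix proteoglycan, at 0.47 (SE 0.15). This median was −0.001 without APB-R3 replicate 3. TGF-beta response genes were split into 13 higher and 14 lower (adjusted p = 0.972). Their median of −0.0004 turned with DESeq2 size factors (0.001) or no scaling beyond library size (0.004). The IL-18 and IL-1 receptor pathway was higher in 12 of 19 members (median 0.01, −0.01 without APB-R3 replicate 3, adjusted p = 0.971), with Il1rn, the IL-1 receptor antagonist, at 0.42 (SE 0.16), or 0.14 without APB-R3 replicate 1. In the collagen, quiescence, TGF-beta and IL-18 lists 0 members passed when adjusted over the list alone.

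Among the stress, signalling and metabolic lists none passed. The adjusted p was 0.590 for interferon response genes, led by Gbp2 at 0.65 (SE 0.23), and 0.995 for inflammasome genes, of which only Il1b passed when adjusted over the list alone. It was 0.971 for p53 targets, led by Pmaip1 at 0.43 (SE 0.35), and 0.783 for the unfolded protein and integrated stress response, led by Psat1 at −0.32 (SE 0.17). Immediate early genes had 0.971, with Klf2 at −0.92 (SE 0.45), and YAP targets 0.300, with Tead1 at −0.21 (SE 0.10). Lipid droplet and retinoid storage genes had 0.783, with the retinol dehydrogenase gene Rdh10 at 0.39 (SE 0.24). Glycolysis and hypoxia genes had 0.132, with Gapdh at 0.26 (SE 0.13), and NRF2 targets 0.163, with the superoxide dismutase gene Sod2 at 0.42 (SE 0.13), or between 0.22 and 0.57 with 1 library left out. Both passed without APB-R3 replicate 2, with adjusted p of 0.0278 and 0.0200, in ranges over all alternatives up to 0.930 and 0.939. In all 6 libraries the adjusted p of both was 0.807 with an estimated correlation and 0.748 with fry. With the preset correlation, the adjusted p was 0.395 for nuclear genes of the respiratory chain, with Uqcrb at 0.21 (SE 0.10). It was 0.974 for mitochondrially encoded genes, with ND2 at −0.11 (SE 0.10), and 0.971 for lysosome and autophagy genes. In these lists, inflammasome genes aside, 0 members passed when adjusted over the list alone. In the p53 and mitochondrial lists, as in the TGF-beta and IL-18 lists and those of cholangiocytes and portal fibroblasts, the median, the mean and the test differed in sign.

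Markers of other liver cell types were measured beside the stellate cell genes, and all values are those of the whole cultures. Liver endothelial markers had a median of 292 CPM over the 6 libraries, above 95.8% of the tested genes, with Lyve1 at 1715 ± 126 CPM, Cdh5 at 1149 ± 128 CPM and Kdr at 889.9 ± 59.7 CPM (SD, n = 6). Macrophage and Kupffer cell markers had a median of 45.1 CPM, contractile genes 137 CPM, collagens 8.89 CPM and genes of quiescent stellate cells 7.15 CPM. Hepatocyte markers had a median of 1.03 CPM, and those of cholangiocytes 0.566 CPM, of portal fibroblasts and mesothelium 0.696 CPM, of neutrophils 0.127 CPM and of lymphocytes 0.0159 CPM. Between the groups, endothelial markers had a median log2 fold change of −0.07 (adjusted p = 0.190), with Vwf (1.45 CPM) at −1.49 (SE 0.72). They passed without vehicle replicate 1 (median −0.12, adjusted p = 0.0294) or APB-R3 replicate 3 (−0.08, 0.0486), in a range up to 0.964. Their median was −0.03 without APB-R3 replicate 1. In all 6 libraries they had 0.909 with an estimated correlation and 0.877 with fry. Macrophage markers had a median log2 fold change of 0.08 (adjusted p = 0.201), with the co-receptor gene Cd14 at 0.33 (SE 0.16). Their median was −0.01 without vehicle replicate 3 and −0.05 without APB-R3 replicate 3. This list passed at 0.23 without vehicle replicate 2 and at 0.14 without APB-R3 replicate 2, in a range of adjusted p up to 0.987, and in all 6 libraries it had 0.926 with an estimated correlation and 0.952 with fry. Hepatocyte markers were lower in 7 of 8 tested members (median −0.47, adjusted p = 0.0962), and the median turned to 0.10 without vehicle replicate 2. The list passed, with medians in brackets, on leaving out vehicle replicate 1 (−0.74) or 3 (−0.93) or APB-R3 replicate 2 (−0.85) or 3 (−0.77), in a range of adjusted p up to 0.919, and in all 6 libraries it had 0.807 with an estimated correlation and 0.851 with fry. Hpx, Fgb and Alb passed when adjusted over that list alone, the last 2 named after their values were seen. Cholangiocyte markers had adjusted p = 0.972, with Spp1 at 0.21 (SE 0.16), and markers of portal fibroblasts and mesothelium 0.971, with Dpp4 at −0.26 (SE 0.15). The lymphocyte and neutrophil lists had 2 and 3 tested members and were not tested as lists. Their members Klrb1c and S100a9 had log2 fold changes of 1.11 (SE 0.68) and −1.41 (SE 0.89), the latter −0.030 without vehicle replicate 1. Over the 6 libraries Klrb1c was at 1.21 CPM and S100a9 at 1.30 CPM. Hepatocyte markers aside, 0 members of these lists passed when adjusted over the list alone.

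**Figure D3:**
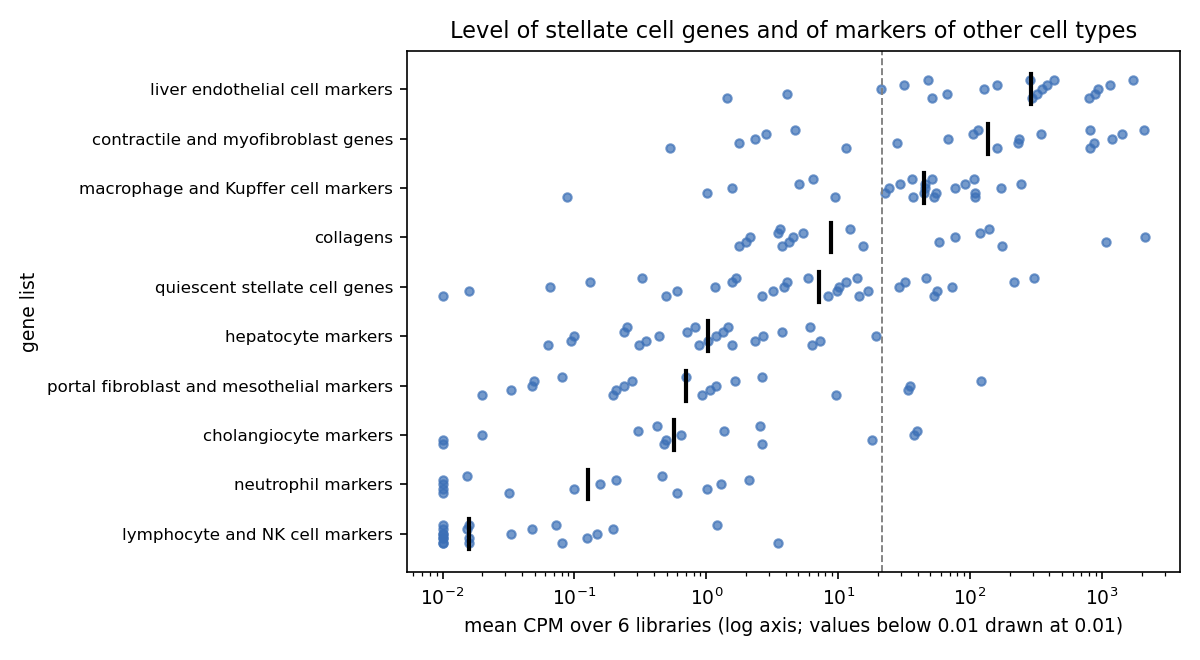
Mean CPM over the 6 libraries, on a log axis, of each member of 10 gene lists (blue points) with the list median (black bar); values under 0.01 CPM are drawn at 0.01 and the dashed line is the mean over libraries of the median tested gene. Liver endothelial markers have a median of 292 CPM, genes of quiescent stellate cells 7.15 CPM and hepatocyte markers 1.03 CPM.

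The libraries did not group by treatment. Spearman correlations of CPM over the tested genes ran from 0.982 to 0.989 within groups and from 0.982 to 0.989 between groups. The mean distance between libraries of different groups minus that within groups was −0.442 on the log2 CPM scale, with a one-sided exact permutation p of 0.9 over 10 splits, where the smallest possible p is 0.1.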

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

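Leaving out both APB-R3 replicate 1 and vehicle replicate 2, and limma-voom with library quality weights, were chosen after seeing the data. The other alternatives were planned. The quality weight was 0.801 for vehicle replicate 2 and 0.848 for APB-R3 replicate 1. It was 0.812 for APB-R3 replicate 2, which was kept in, and between 1.04 and 1.32 in the other libraries. The cause of a change below was not tested unless given. In 15 of 17 alternatives edgeR, DESeq2 or limma-voom called 0 genes, with between 311 and 674 genes at an unadjusted p under 0.05. With no low-count filter 20 genes passed, 8 higher and 12 lower. Some of them, such as Il1b and Mmp9, were also tested in the main fit and did not pass there. Of the 40 named genes, 35 kept their direction in every alternative that tested them.

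The list calls moved more. Camera with an estimated correlation and fry passed 0 lists, each with 1 list at an unadjusted p under 0.05, and changed no median: −0.17 for cholesterol and fatty acid synthesis, 0.17 for the inflammatory list, −0.12 for the cell cycle, −0.085 for matrix glycoproteins and 0.064 for ribosomal proteins. Ribosomal proteins were lost with no low-count filter (0.064) and matrix glycoproteins at 5 CPM in 3 libraries (−0.061). In the same settings hepatocyte markers (−2.27) and quiescence genes (0.098) passed in their place, respectively. With the main filter, camera with an estimated correlation gave both lists an adjusted p of 0.807. The median of TGF-beta response genes turned with DESeq2 size factors (0.0014), with library size only (0.0040) and at 5 CPM (0.00042).

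With both libraries left out, 0 genes passed in edgeR (523 at an unadjusted p under 0.05) and 1 list did, macrophage markers (0.25), whose adjusted p in all 6 libraries was 0.926 with an estimated correlation. The medians were −0.088 for matrix glycoproteins, −0.041 for the cell cycle, −0.10 for cholesterol and fatty acid synthesis and 0.021 for ribosomal proteins, all lost, with fewer samples. They turned to −0.089 for the inflammatory list, 0.0015 for TGF-beta response genes and 0.045 for hepatocyte markers, and the log2 fold change to 0.036 for Ccn2.

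Leaving out each library in turn gave 0 to 1 genes, 0 to 1 of them lower, and 0 to 9 lists. Log2 fold changes ran from −0.16 to 0.0013 for Ccn2, −0.17 to 0.043 for Col1a1, −0.088 to 0.10 for Col3a1, −0.074 to 0.72 for Il18bp and −0.049 to 0.29 for Tgfb1. In the other named genes whose change kept its direction but was more than 1.5 times smaller without 1 library, they ran from 0.87 to 1.91 for Acod1, −0.35 to −0.16 for Col1a2, −0.80 to −0.24 for Des, −0.34 to −0.12 for Dpp4, 0.098 to 0.34 for Gapdh, −4.99 to −1.12 for Hpx, 0.019 to 0.85 for Il18, 0.21 to 3.80 for Il1b, 0.14 to 0.59 for Il1rn, 0.72 to 1.40 for Klrb1c, −0.20 to −0.0090 for ND2, 0.27 to 0.69 for Pmaip1, 0.23 to 0.61 for Rdh10, 0.078 to 0.23 for Rps27a, −1.97 to −0.030 for S100a9, −1.39 to −0.58 for Saa3, 0.22 to 0.57 for Sod2, 0.068 to 0.41 for Spp1 and 0.10 to 0.24 for Timp1. List medians ran from −0.13 to −0.080 for matrix glycoproteins, −0.039 to 0.27 for the inflammatory list, −0.17 to −0.059 for the cell cycle, −0.29 to −0.061 for cholesterol and fatty acid synthesis and 0.015 to 0.11 for ribosomal proteins. They ran from −0.0014 to 0.17 for quiescence genes, −0.049 to 0.0061 for TGF-beta response genes, −0.011 to 0.055 for the IL-18 pathway, −0.049 to 0.23 for macrophage markers and −0.93 to 0.10 for hepatocyte markers.

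The labels do not say that the replicate numbers pair cultures, so the main fit had no block, as set before the data were examined. Same-numbered libraries had correlations of 0.0225, 0.0270 and 0.0480 between their deviations from the group means. All 6 libraries correlated best with their own number. Deviations from a group mean cancel within the group, so these 6 matches are not independent. With correlations this small they are at most a weak hint of pairing. With the replicate block 0 genes passed (539 at an unadjusted p under 0.05) and 6 lists did, hepatocyte markers being the added one (−0.48). Without the block, camera with an estimated correlation gave hepatocyte markers an adjusted p of 0.807. Il18r1 and Il18rap had 1 count each, and whether depth, expression or the assignment of reads kept them low was not tested.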

Other observations

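All tests of this part except the counts of other splits were chosen after the result was seen, as were the genes it names other than Ccn2, Col1a1 and Hpx. Among the most abundant messages of these cultures, in CPM over 6 libraries (SD), were Actb at 6739 ± 379, Sparc, a matrix glycoprotein of mesenchymal and endothelial cells, at 6279 ± 299, and Ctla2a, a cathepsin inhibitor, at 5115 ± 480. Further down came Ccn2 at 3379 ± 267, the endothelial and myeloid receptor gene Cd93 at 3150 ± 145, the retinoic acid-degrading enzyme gene Cyp26b1 at 2349 ± 334 and the basement membrane collagen gene Col4a1 at 2112 ± 65.2. The fibrillar collagen gene Col1a1 stood at 139 ± 14.6 CPM. APB-R3 replicate 2 held transcripts of skeletal muscle, with 67 counts of Acta1 against 0 to 9 in the other libraries and 55 counts of Myh4 against 0 to 20.

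Inflammatory genes were high in APB-R3 replicate 1. The inflammatory list had a median log2 ratio of 0.49 in that library over the other 5 (interval 0.36 to 0.81), with 260 CPM of Cxcl2 and 19.1 CPM of Tnf on plain library totals and 30 counts of Il12b, which had 0 in the other libraries. In APB-R3 replicates 2 and 3 the median over vehicle was −0.022 (interval −0.084 to 0.019), against 0.49 in replicate 1, so these libraries did not show the rise. The interval is over genes, whose estimated correlation was 0.490, and leaves out the spread between libraries. It therefore cannot exclude a response shared by all APB-R3 libraries. The 23 tested macrophage markers had a median ratio of −0.058 (interval −0.30 to −0.021) in APB-R3 replicate 1, so as a set they were not higher there. This interval has the same limit, with an estimated correlation of 0.498, and cannot exclude more macrophages in that library. What set this library apart was not tested.

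Hepatocyte genes were high in vehicle replicate 2, with 339 counts of Fgb against 0 to 14 elsewhere, 153 counts of Saa2 against 0 to 2, and 191 of Alb against 24 to 68. Of the 14 hepatocyte markers with at least 20 counts, leaving out Hpx, Fgb and Alb, in which the pattern was first seen, 10 had their highest CPM there. This is short of the share set for hepatocyte RNA in that library and above the share set against it, so that explanation stays open. None of these markers is in another list, and how many of them pure stellate cells express was not analysed here. A fall of hepatocyte genes with APB-R3 cannot be told apart from no fall. Over vehicle replicates 1 and 3 alone the median difference in log2(CPM + 1) was 0.0055 (interval −0.42 to 0.11), against −0.61 over all vehicle libraries, and the few counts keep it open.

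Endothelial transcripts were abundant in all 6 libraries. At least 17 of the 20 endothelial markers lay above the median tested gene in every library, with Lyve1 at 1715 CPM and Cdh5 at 1149 CPM, while genes of quiescent stellate cells had a median of 7.15 CPM. None of the 20 genes is in another list, how many of them pure stellate cells express was not analysed here, and the labels used here name no sort that would remove endothelial cells. Lrat, the retinol-esterifying enzyme gene of stellate cells, was at 1.68 CPM. Between 15 and 18 of the 24 macrophage markers also lay above the median tested gene in each library. As sets, the endothelial and macrophage markers argue against cultures of stellate cells alone. Which cells the transcripts come from was not tested, and it is open whether the cultures are mixed or mainly endothelial. A value given here for stellate cells is therefore that of the whole culture.

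The 6 libraries can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 0 genes and the highest of the others 2. Any split gives at least 0 genes whatever the data, so this comparison cannot decide anything. At an unadjusted edgeR p under 0.05 the real split gave 425 genes and the others between 417 and 772. By that count the real split did not stand out. For lists the real split gave 5 and the highest of the others 10, with 5 of the 10 splits at 5 or more. With no low-count filter the real split gave 20 genes and the highest of the others 43, with 7 of the 10 at 20 or more. Of those 20 genes, 18 had their highest CPM in APB-R3 replicate 1 (all 8 higher genes) or vehicle replicate 2 (10 of the 12 lower genes). The genes that set these libraries apart, such as Il1b and Hpx, are among the 20, so this count is no independent test. A highest CPM in a library also does not show that a call rests on it. Mmp9 is counted, yet its log2 fold change ran from 0.62 to 1.06 with each library left out. Single libraries thus stay an untested candidate explanation of the calls.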
